A study of Caenorhabditis elegans with 46 samples.

How the data were processed

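Total RNA came from whole worms of the L1 stage, per the labels' protocols. Libraries were built from at least 20 ug of it by a published protocol that the labels cite, and small RNA of 18 to 30 nt was selected. The 46 libraries were biological replicates, per the series' design text: 2 per genotype and treatment in wild type worms and in 9 transgenic genotypes, and 3 in the rps-5 lines, where 2 of the 3 come from the same line. Libraries are named here by their number in the labels. What these numbers mark is not given in the sources used here. Some genotypes have adjoining numbers, such as myo-3 with henn-1 (49401 to 49404) and without (49405 to 49408), and others lie apart, such as rab-3 (32795 to 32798) and rgef-1 (37022 to 37025). For genotypes that lie apart, a difference between rounds of preparation or sequencing was not excluded.

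The authors deposited expected counts per mature microRNA arm, 1 table per library, with 916 entries each. Adapter trimming with cutadapt 1.2.1, counting with HTSeq 0.6.1p1 and the genome build WBcel235 are stated per the submitters' processing notes; the aligner and its settings are not given in the sources used here. The unit was read from the values: most were whole numbers, and 20 to 51 arms per library were fractional (more than 1e-06 from a whole number), which held up to 8.95% of a library's counts and is how reads shared between loci appear when they are split. Of the entries, 473 were worm arms and 443 had other names and were 0 in every library. 467 worm arms had at least 1 count. All columns of values were mapped to a library.

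The deposited expected counts were rounded to whole numbers and tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3). Arms were kept by its filter with a minimum count of 10, which left 395 arms and 100% of the counts. Library sizes were scaled with TMM factors, and 1 quasi-likelihood model with robust estimation and a coefficient for each of the 22 combinations of genotype and treatment was fitted to all 46 libraries, because groups of 2 or 3 libraries have to share an estimate of the spread. P-values were adjusted within each comparison by the Benjamini-Hochberg method and called at 0.05. All standard errors come from this fit. Where a group was at 0 counts, the fold is a lower bound with 3 counts over the group in place of 0, and with 1 to 3 counts a ratio with a 95% interval is given. These intervals and lower bounds cover counting error only.

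The comparisons numbered 32: oxidised against untreated in each of the 11 genotypes; the difference in that effect between each of 10 transgenic genotypes and wild type, between the rps-5 lines and 5 others (the mean of the 3 pan-neuronal drivers, elt-2, myo-2, myo-3 and ASE, all henn-1(0)), between henn-1(0) worms and worms with henn-1 for 2 drivers, and between pan-neuronal drivers for 3 pairs. The last was untreated rps-5 lines against untreated wild type worms. Model, comparisons, thresholds, alternatives, lists and the rule for naming arms were fixed before the data were examined. The rule names the arms of lsy-6, miR-1, miR-124 and miR-60 everywhere. Within a genotype it adds the 10 largest called rises and the 5 largest called falls that have the same sign in every oxidised library, and between genotypes the 5 largest called differences each way. All members of 12 lists were also open to naming. These were neuronal, muscle, intestinal, and epidermal, seam or glial microRNAs, and the miR-35, miR-51, miR-58, let-7, miR-64, miR-72, miR-44 and miR-2 families; only the arm of each hairpin with more counts in untreated libraries was used, and some members stand in more than 1 list. miR-62-3p, and arms named again in a comparison other than the one that selected them, were chosen after their values were seen.

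Oxidised libraries were far shallower in some genotypes than in others, which matters most for arms with few counts. The method was tested on simulated data with the depth, group sizes and spread of the real libraries and with 200 of 395 arms changed. As many arms were raised as lowered, unlike in several real comparisons, so the simulation does not measure errors of scaling. edgeR recovered 14.9%, 64.2% and 80.3% of arms changed 2-fold, 4-fold and 8-fold in the wild type comparison (1 of 195 unchanged arms called), 49.3%, 88.1% and 95.5% in the rps-5 comparison (4 called), 26.9%, 76.1% and 86.4% in the elt-2 comparison (1 called), 19.4%, 77.6% and 92.4% for pan-neuronal drivers against rps-5 (3 called), and 8.96%, 32.8% and 62.1% for the henn-1 comparison with myo-3 (6 called). Changes of 4-fold were thus missed in part in each of these 5 comparisons, and most of them in the last. Between replicates, correlations of log2 counts were at least 0.986 in untreated libraries and 0.963 to 0.992 in oxidised ones, no 2 libraries were identical, and the spread exceeded counting error by a chi-square per degree of freedom of at least 54.4.

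Same-numbered oxidised and untreated libraries of a transgenic genotype come from the same transgenic line, per the labels, so they are paired. Their deviations from the group means correlated at −0.0019 to 0.774 over the 10 transgenic genotypes, above 0.1 in 7. The model used no block, and a fit with the line as a replicate block was an alternative. The other alternatives were RLE size factors, total counts without scaling factors, no filter on low counts, the Wald test of DESeq2 1.42.0, leaving out each library in turn, and, within a genotype, a fit of its own libraries alone. Alternatives for the number of arms called in every comparison and for the named arms within genotypes were fixed beforehand. Leave-one-out and own-library fits of named arms, and all alternatives of named arms in the remaining comparisons, were added after seeing the data. Where a scaling moved the median change or the split into higher and lower arms clearly, the report gives it. Of 217 tested hairpins, 215 were matched by name to the genome annotation for position and overlap. Intervals of medians come from 2000 bootstrap draws over hairpins, which treat hairpins as independent and leave out the spread between libraries. Entries with names other than worm arms, and small RNA other than microRNA, which the deposited tables do not hold, were not analysed here.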

Results

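Small RNA was sequenced from whole Caenorhabditis elegans larvae of the L1 stage in 46 libraries, which covered 11 genotypes with and without sodium periodate. Periodate oxidises the free end of a small RNA so that it no longer enters a library, whereas a methylated end is spared. Animal microRNAs usually lack this methyl group, and Ath-HEN1, a plant methyltransferase, adds it. In 10 genotypes Ath-HEN1 was expressed from a driver: rps-5, a ribosomal protein gene active in most cells; rab-3, unc-31 or rgef-1, active across the nervous system; elt-2, active in the intestine; myo-2, active in pharyngeal muscle; myo-3, active in body wall muscle; or ASE, for a pair of taste neurons. In 8 of them the gene of the worm's own small RNA methyltransferase, henn-1, carried a null allele, written henn-1(0), and the myo-3 and ASE drivers were also studied with henn-1 intact. Each genotype had 2 libraries per condition, except rps-5 with 3. Untreated libraries held 10700000 to 43300000 counts and oxidised libraries 426000 to 35300000. The oxidised wild type pair averaged 636000 ± 298000 (SD, n = 2), the ASE pair with henn-1 950000 ± 448000 and the ASE henn-1(0) pair 1030000 ± 31800. In the rps-5 lines the mean was 12900000 ± 2510000 (SD, n = 3). Changes are given as log2 of oxidised over untreated counts after scaling to a common effective library size. They carry the standard error (SE) of a fit over all 46 libraries, with n as above. A positive value therefore means a rise relative to the scaled library, which is not the same as a gain of share of all counts. The 4 marker microRNAs below were followed throughout. They were lsy-6 (chromosome V, 10647232 to 10647304, plus strand, between genes), which sets the left ASE neuron apart from the right; miR-124 (chromosome IV, 11871738 to 11871833, plus strand, in an intron of trpa-1), a neuronal microRNA conserved in mammals; miR-60 (chromosome II, 6328702 to 6328799, minus strand, between genes), abundant in the intestine; and miR-1 (chromosome I, 6172662 to 6172757, minus strand, between genes), the conserved muscle microRNA.

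Wild type worms, which carried no plant enzyme, gave the background of the method. All 4 markers fell on oxidation: miR-124-3p fell by 4.71 ± 0.42, miR-1-3p by 4.47 ± 0.43, miR-60-3p by 3.89 ± 0.45 and lsy-6-3p by 3.38 ± 0.48 on the log2 scale. As mean shares of all counts (n = 2) they fell less: miR-124-3p from 0.848% to 0.151%, miR-1-3p from 2.50% to 0.512%, miR-60-3p from 1.93% to 0.616% and lsy-6-3p from 0.0111% to 0.00512%. The passenger arm miR-1-5p, lower at −1.60 ± 0.51, gained share, from 0.00758% to 0.0105%, stood at 0.82 with RLE factors and 0.48 with total counts, and lost its call without library 32794 (−1.21). A smaller set rose. miR-798-3p rose by 6.21 ± 0.57 (adjusted p = 5.11e-12, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), miR-8198-5p by 6.30 ± 0.65, miR-8198-3p by 6.14 ± 0.56 and miR-78-3p by 6.10 ± 0.77. miR-62-3p rose by 1.82 ± 0.36 and alone made up 24.4% and 36.1% of the counts in the 2 oxidised libraries; its hairpin lies in an intron of ugt-50 (chromosome X, 12692608 to 12692665, plus strand). Without library 32794 lsy-6-3p stood at −4.06 and miR-60-3p at −4.62, without 34093 miR-62-3p stood at 1.22 and miR-8198-5p at 5.71, and without 32793 miR-78-3p stood at 6.74. miR-1817-5p was at 0 counts after oxidation and was at least 6.50-fold lower. Of 395 arms tested, 275 changed, 82 higher and 193 lower, and 271 of them moved the same way in each oxidised library against the mean of the untreated ones. The median arm stood at −2.20. Size factors of the RLE kind moved it by 2.37 and gave 138 higher and 83 lower arms, and total counts alone moved it by 2.09 and gave 125 and 90.

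The broad rps-5 driver raised many microRNAs after scaling. miR-1-3p rose by 1.17 ± 0.31 (n = 3 libraries per condition), miR-793-3p, a relative of let-7, by 1.33 ± 0.27, miR-72-5p by 1.26 ± 0.27, and lin-4-3p, the passenger arm of a regulator of larval timing, by 2.29 ± 0.54. lsy-6-3p fell by 1.98 ± 0.36 and miR-60-3p by 1.14 ± 0.33, while miR-124-3p did not pass the test at 0.22 ± 0.29 (adjusted p = 0.551, edgeR). Of the 82 arms that had risen in wild type worms, 41 also rose here and 11 fell. miR-798-3p fell by 7.58 ± 0.59 and miR-8198-5p by 6.64 ± 0.65, and miR-78-3p went from 623 counts to 2, a ratio of 309 (95% counting interval 85.2 to 2558). In total 227 arms changed, 138 higher and 89 lower. Of these, 226 moved the same way in each oxidised library against the mean of the untreated libraries of its line. RLE factors moved the median by −0.23 and gave 94 higher and 97 lower, and total counts moved it by 0.27. A fit of the rps-5 libraries alone called 134 arms, 41 higher and 93 lower, and left miR-1-3p (0.69) and lin-4-3p (1.87) short of the threshold. lin-4-3p stood at 3.33 without library 42745, and miR-798-3p at −9.02 and miR-8198-5p at −8.39 without 42752.

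With a driver for the whole nervous system, 7 or 8 of 12 neuronal arms rose, whereas miR-1-3p fell and its passenger arm miR-1-5p rose. miR-124-3p rose by 2.47 ± 0.38 in the rgef-1 lines, 1.44 ± 0.36 in the unc-31 lines and 0.98 ± 0.36 in the rab-3 lines. lsy-6-3p rose by 1.12 ± 0.43, 1.2 ± 0.43 and 0.96 ± 0.43 in the same order (adjusted p = 0.0193, 0.0131 and 0.0426, edgeR). Larger gains were those of miR-793-3p (4.93 ± 0.39, 4.60 ± 0.38 and 3.65 ± 0.37), miR-1821-3p (4.69 ± 0.44, 4.17 ± 0.43 and 3.51 ± 0.41), miR-790-3p (5.38 ± 0.97, 4.62 ± 0.94 and 3.99 ± 0.90) and miR-90-5p (5.11 ± 0.69, 4.52 ± 0.67 and 4.23 ± 0.66). miR-60-3p fell by 3.58 ± 0.44 with rgef-1 and by 3.42 ± 0.44 with unc-31, but stood at −0.74 ± 0.40 with rab-3 (adjusted p = 0.0934, edgeR). miR-1-3p fell by 1.27 ± 0.38, 1.34 ± 0.38 and 1.89 ± 0.38 with rgef-1, unc-31 and rab-3. The passenger arm miR-1-5p went the other way and rose by 2.81 ± 0.52, 2.54 ± 0.52 and 1.98 ± 0.51 in the same order. miR-60-5p rose by 1.68 ± 0.49 with rab-3 but stood at −2.27 ± 0.51 with unc-31 and −1.87 ± 0.50 with rgef-1. For these passenger arms the alternatives are not given here. miR-43-3p, of the miR-2 family, fell by 6.92 ± 0.39 with rab-3. Of the 12 neuronal arms tested, 8 rose and 3 fell with rgef-1, 7 and 3 with unc-31, and 7 and 2 with rab-3, the same counts adjusted over the list alone. Changed arms numbered 286 with rgef-1 (156 higher, 130 lower), 269 with unc-31 (124 and 145) and 288 with rab-3 (143 and 145). The median stood at 0.11, −0.42 and −0.04 and shifted with RLE factors by −0.31, 0.18 and −0.19 and with total counts by 0.19, 0.73 and 0.45, the last giving 155 higher and 111 lower arms with unc-31. Some of the marker calls rested on the method. With RLE factors and without a filter on low counts lsy-6-3p fell short with rab-3 (0.75 and 0.85) and rgef-1 (0.79 and 0.98). miR-1-3p with unc-31 did so with total counts (−0.52), without a filter (−0.67) and in a fit of its own libraries (−0.81). miR-60-3p with rab-3 passed as lower with RLE factors or DESeq2 (−0.96 in each) and in a fit of its own libraries (−0.81). Single libraries decided other calls. lsy-6-3p lost its call without rab-3 libraries 32795 (0.87), 32796 (1.05) or 32797 (0.68), unc-31 libraries 32951 (0.99) or 32953 (0.20) and rgef-1 libraries 37023 (0.70) or 37024 (0.97). miR-124-3p lost it without rab-3 libraries 32795 (0.89) or 32798 (0.92) and unc-31 library 32953 (0.30), and miR-1-3p did so without unc-31 library 32950 (−0.96) or rgef-1 library 37023 (−1.03). miR-60-3p also passed the test with rab-3 once library 32797 was left out (−1.25), and miR-1-3p then stood at −2.72. miR-790-3p stood at 4.76 with rab-3 without 32795 and at 3.98 with unc-31 without 32954.

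The intestinal driver elt-2 kept a different set. miR-60-3p rose by 1.47 ± 0.41 (adjusted p = 0.00147, edgeR) and its passenger arm miR-60-5p by 2.95 ± 0.51, but the other 2 of the 3 listed intestinal arms fell, miR-240-3p by 2.45 ± 0.51 and miR-786-3p by 3.38 ± 0.46, the same calls adjusted over the list alone and under each scaling. The larger gains included miR-1020-5p (4.88 ± 0.45), miR-243-5p (4.68 ± 0.47), miR-243-3p (4.63 ± 0.41) and miR-789-1-5p (4.62 ± 0.57; 5.68 without library 36212 and 3.57 without 36213). Among these arms, miR-243-3p and miR-789-1-5p also rose in wild type worms without the plant enzyme, by 4.38 ± 0.41 and 2.65 ± 0.53. In the miR-64 family 4 of 5 arms rose, among them miR-63-3p by 3.30 ± 0.36 and miR-65-5p by 2.71 ± 0.35. lsy-6-3p fell by 5.12 ± 0.51, miR-124-3p by 4.57 ± 0.41 and miR-1-3p by 3.82 ± 0.41, and lsy-6-5p, at 0 counts after oxidation, was at least 29.2-fold lower. Of 12 neuronal arms, 11 fell, the same number adjusted over the list alone and with RLE factors, which added 1 that rose. In all 296 arms changed, 111 higher and 185 lower, with the median at −1.43; RLE factors moved the median by 0.79.

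Both muscle drivers kept miR-1. Its mature arm miR-1-3p rose by 3.51 ± 0.41 with myo-3 in henn-1(0) worms, 2.85 ± 0.40 with myo-3 and henn-1 intact, and 2.34 ± 0.39 with myo-2, where the passenger arm miR-1-5p rose by 6.00 ± 0.60, or 4.51 without oxidised library 42756. In pharyngeal muscle the larger gains included miR-251-3p (6.96 ± 0.74), miR-236-5p (5.59 ± 0.56), miR-55-5p (5.45 ± 0.50), miR-82-5p (5.19 ± 0.50) and miR-245-5p (5.16 ± 0.56). In body wall muscle of henn-1(0) worms they included miR-8211-3p (5.22 ± 0.70), miR-86-3p (4.94 ± 0.61), miR-4806-3p (4.83 ± 0.51), miR-50-3p (4.50 ± 0.50) and miR-67-5p (4.39 ± 0.65). With henn-1 intact the larger gains included miR-8198-5p (6.67 ± 0.67), miR-8198-3p (6.00 ± 0.56) and miR-798-3p (5.67 ± 0.56). miR-124-3p fell by 4.08 ± 0.40 with myo-2 and by 5.29 ± 0.43 and 5.41 ± 0.43 with myo-3 without and with henn-1, and miR-60-3p by 3.07 ± 0.43, 4.19 ± 0.45 and 5.14 ± 0.47. lsy-6-3p fell by 5.45 ± 0.55 with myo-2 and by 5.36 ± 0.53 with myo-3 in henn-1(0) worms, and with henn-1 only 3 counts were left after oxidation, a ratio of 71.2 (95% counting interval 24.3 to 345) of untreated over oxidised. Without oxidised myo-2 library 42756 miR-251-3p stood at 6.02, miR-236-5p at 4.95 and miR-245-5p at 4.56. With myo-3 in henn-1(0) worms miR-8211-3p stood at 6.87 without library 49405 and at 3.84 without 49406, and lsy-6-3p at −6.11 without 49406. With henn-1 miR-60-3p stood at −4.25 without 49401. miR-2210-3p with myo-2 and miR-8191-5p with myo-3 in henn-1(0) worms were at 0 counts, at least 16.9-fold and at least 46.3-fold lower. The myo-2 lines had 264 changed arms (81 higher, 183 lower, median −1.61), the myo-3 henn-1(0) lines 275 (74 and 201, median −1.72) and the myo-3 lines with henn-1 233 (108 and 125, median −0.99). RLE factors moved the medians by 1.24, 1.70 and 0.72 and gave 113 and 111 arms with myo-2 and 126 and 118 with myo-3 in henn-1(0) worms.

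With the ASE driver lsy-6 rose. In henn-1(0) worms lsy-6-3p rose by 4.60 ± 0.49 (adjusted p = 1.23e-09, edgeR) and lsy-6-5p by 4.52 ± 0.50. miR-790-3p (7.48 ± 1.07), miR-1821-3p (6.99 ± 0.49), miR-2953-3p (6.69 ± 0.53), miR-791-5p (6.40 ± 0.61), miR-793-3p (5.46 ± 0.40) and miR-790-5p (5.37 ± 0.48) gained more still, and miR-124-3p rose by 1.72 ± 0.37. miR-54-3p fell by 2.38 ± 0.32, miR-60-3p by 1.33 ± 0.40 and miR-1-3p by 1.19 ± 0.37. With henn-1 intact lsy-6-3p rose by 1.36 ± 0.43 (adjusted p = 0.00557, edgeR), miR-1821-3p by 3.27 ± 0.41 and miR-793-3p by 2.33 ± 0.35, while miR-8198-5p (7.37 ± 0.68), miR-798-3p (6.41 ± 0.57) and miR-789-2-3p (6.40 ± 0.41) were among the arms that gained more. miR-1-3p fell there by 5.00 ± 0.44 and miR-60-3p by 4.72 ± 0.46, and miR-247-3p, at 0 counts after oxidation, was at least 26.1-fold lower. miR-124-3p fell by 1.84 ± 0.37 with the main scaling but stood at 0.53 with RLE factors and 0.02 with total counts. In henn-1(0) worms 148 arms changed (69 higher, 79 lower, median −0.58) and with henn-1 284 (93 and 191, median −1.83). RLE factors moved the medians by 0.46 and 2.37 and gave 78 and 43 arms and 158 and 88, and total counts moved them by 0.64 and 1.85 and gave 83 and 33 arms and 139 and 109. In henn-1(0) worms the falls of miR-1-3p and miR-60-3p lost their calls with RLE factors or DESeq2 (−0.72 and −0.86 in each), total counts (−0.56 and −0.68) and no filter on low counts (−0.76 and −0.88). miR-1-3p also lost it without library 42749 (−0.93) or 42750 (−0.87) and miR-60-3p without library 42748 (−1.16). lsy-6-5p stood at 3.68 without 42750 and miR-790-3p at 8.21 without 42749.

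**Figure D1:**
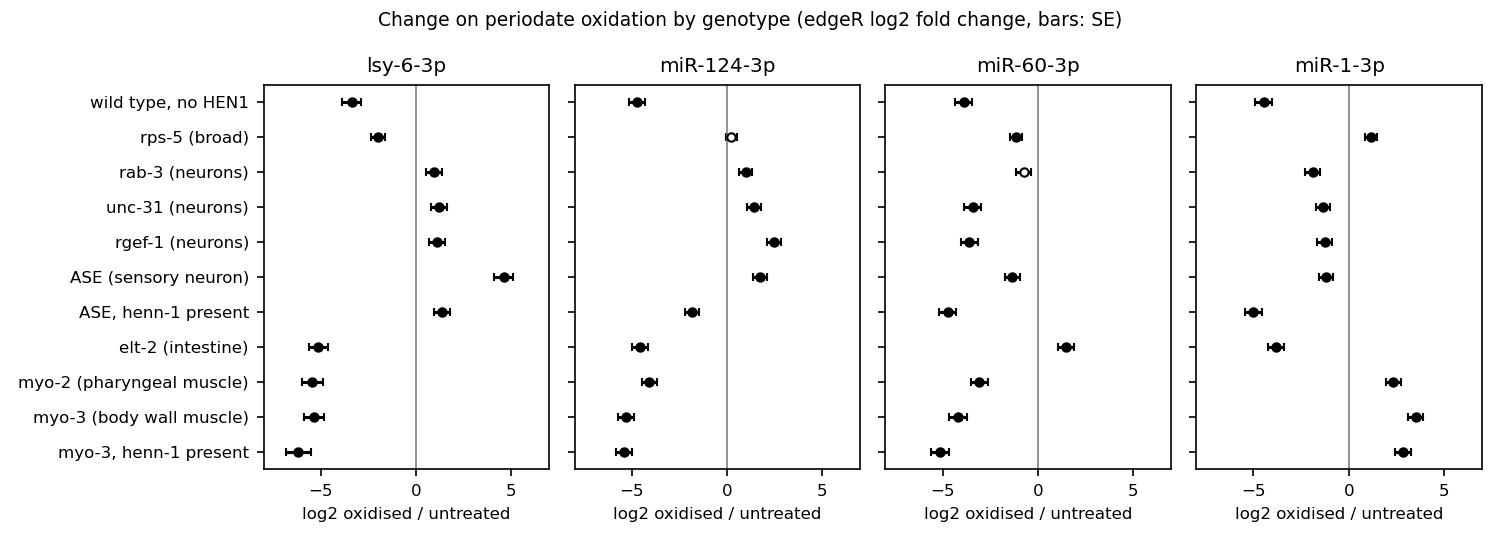
Log2 change on oxidation (horizontal axis, bars show the SE) of lsy-6-3p, miR-124-3p, miR-60-3p and miR-1-3p in the 11 genotypes (vertical axis), with open circles where the edgeR test was not passed and with the lsy-6-3p value of the myo-3 lines with henn-1 resting on 3 counts. lsy-6-3p stood highest at 4.60 in ASE henn-1(0) worms, miR-60-3p at 1.47 with elt-2 and miR-1-3p at 3.51 with myo-3, while miR-124-3p in the rps-5 lines and the ASE lines with henn-1 changed sign with RLE factors.

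The next comparison asked which microRNAs neurons keep beyond what cells at large keep, as the mean effect of the rab-3, unc-31 and rgef-1 lines against that of the rps-5 lines. Neuronal microRNAs were higher: miR-234-3p by 3.10 ± 0.38, lsy-6-3p by 3.07 ± 0.44, miR-793-3p by 3.07 ± 0.34, miR-1821-3p by 2.99 ± 0.39, miR-76-3p by 2.66 ± 0.36, miR-87-3p by 2.10 ± 0.30 and miR-124-3p by 1.41 ± 0.36 (adjusted p = 0.00103, edgeR; 6 oxidised neuronal libraries against 3). Of the 12 neuronal arms tested, 10 were higher and 1, miR-82-3p of the miR-58 family, was lower by −2.89 ± 0.28. miR-1-3p, the single muscle arm, was lower by −2.67 ± 0.38, as were all 3 intestinal arms, led by miR-240-3p (−1.99 ± 0.46) and miR-60-3p (−1.44 ± 0.40). Of 5 epidermal, seam or glial arms 4 were lower, among them miR-235-3p (−2.67 ± 0.39), miR-244-5p (−2.30 ± 0.37) and the glial miR-228-5p (−2.04 ± 0.24). All 8 arms of the miR-35 family, which is made in oocytes and embryos, were lower, from miR-42-3p (−2.06 ± 0.31) to miR-35-3p (−3.67 ± 0.80; −2.81 without rps-5 library 42752). In the remaining families 4 of 7 let-7 arms were higher and 1 lower, 2 of 6 miR-51 arms higher and 1 lower, 1 of 4 miR-2 arms higher and 1 lower, and 3 of 5 miR-58 arms, 4 of 5 miR-64 arms, 3 of 3 miR-72 arms and 3 of 4 miR-44 arms lower. Adjusted over the list alone, all 12 lists had the same counts, and with RLE factors or total counts only the miR-51 family (3 or 4 higher) and the miR-72 family (2 lower) had others. In total 226 arms differed, 107 higher and 119 lower, and the scalings moved the median by 0.12 and 0.19.

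Against the same rps-5 lines, the intestinal driver gave higher miR-392-5p (3.98 ± 0.82), miR-248-5p (3.90 ± 0.81), miR-65-3p (3.67 ± 0.65) and miR-60-3p (2.62 ± 0.52, adjusted p = 6.67e-05, edgeR). The other 2 of the 3 intestinal arms were lower, 1 of them with RLE factors, and the calls adjusted over the list alone were the same. miR-248-5p stood at 4.77 without library 36212 and miR-392-5p at 2.97 without 42745. All 5 arms of the miR-64 family were higher, under each scaling and adjusted over the list alone, with miR-63-3p at 3.06 ± 0.44 and miR-64-5p at 1.62 ± 0.40. miR-244-5p was lower at −5.13 ± 0.51, as were miR-1-3p (−5.0 ± 0.51), miR-124-3p (−4.79 ± 0.49) and lsy-6-3p (−3.14 ± 0.58), and 11 of 12 neuronal arms were lower, 10 with RLE factors. In all 214 arms differed, 66 higher and 148 lower. The median moved by 1.02 with RLE factors, which gave 109 and 112, and by −0.22 with total counts.

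Pharyngeal muscle stood above the rps-5 lines in miR-251-3p (6.20 ± 0.82), miR-255-5p (5.27 ± 0.72), miR-245-5p (4.51 ± 0.64), miR-236-5p (4.41 ± 0.62), miR-1-5p (4.39 ± 0.66) and miR-72-5p (2.17 ± 0.42), and in miR-1-3p by 1.16 ± 0.48 (adjusted p = 0.042, edgeR). Body wall muscle in henn-1(0) worms stood above them in miR-2210-5p (5.03 ± 0.99), miR-86-3p (4.35 ± 0.70), miR-67-5p (4.31 ± 0.79), miR-2-5p (4.29 ± 0.63), miR-2-3p (2.94 ± 0.38) and miR-1-3p (2.34 ± 0.48). miR-228-5p was lower in both, at −4.03 ± 0.32 and −3.99 ± 0.32, as was miR-124-3p, at −4.29 ± 0.48 and −5.50 ± 0.50. The miR-35 family was lower in 8 of 8 arms with either driver and the miR-72 family in 3 of 3 with myo-3, miR-72-5p at −3.70 ± 0.43. Of 12 neuronal arms, 9 were lower with myo-2 and 11 with myo-3, where miR-2-3p was the 1 that was higher. With RLE factors 6 were lower and 2 higher with myo-2, and 7 lower with myo-3; the counts adjusted over the list alone were the same. Arms that differed numbered 193 with myo-2 (42 higher, 151 lower) and 237 with myo-3 (58 and 179). RLE factors moved the medians by 1.47 and 1.93 and gave 90 and 72 arms and 110 and 83, and total counts moved them by −0.27 and −0.29. miR-1-3p with myo-2 lost its call with total counts (0.97) and without rps-5 libraries 36208, 42746 or 42751 or myo-2 libraries 42754, 42755 or 42756 (0.89 to 1.23), and without library 42756 miR-1-5p with myo-2 stood at 2.90, miR-251-3p at 5.26, miR-255-5p at 4.49, miR-245-5p at 3.90 and miR-236-5p at 3.77. With myo-3 miR-2-5p stood at 4.88 and miR-67-5p at 5.03 without 42746, and miR-2210-5p at 5.90 without 49407.

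The ASE neurons in henn-1(0) worms stood above the rps-5 lines in lsy-6-5p (6.67 ± 0.64; 5.83 without library 42750), miR-2953-3p (6.60 ± 0.61), lsy-6-3p (6.58 ± 0.61, adjusted p = 8.33e-11, edgeR), miR-1821-3p (5.86 ± 0.53), miR-790-5p (5.24 ± 0.55) and miR-793-3p (4.13 ± 0.45). miR-8198-5p was higher by 6.81 ± 0.89 (8.56 without 42752), which reflects its fall of 6.64 ± 0.65 in the rps-5 lines, for it stood at 0.17 ± 0.56 with ASE. miR-87-3p was higher by 1.94 ± 0.38 and miR-124-3p by 1.50 ± 0.46. miR-4807-3p was lower at −3.58 ± 0.54, with miR-65-5p (−2.41 ± 0.44), miR-1-3p (−2.36 ± 0.48) and miR-64-5p (−2.27 ± 0.41). Of 12 neuronal arms 9 were higher under each scaling and adjusted over the list alone, and 2 were lower, 1 of them with total counts. In all 139 arms differed, 68 higher and 71 lower. RLE factors gave 92 and 28 and moved the median by 0.70, total counts gave 78 and 45 and moved it by 0.37, and without oxidised ASE library 42750 the number was 91. miR-124-3p lost its call without untreated ASE library 42749 (1.29).

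**Figure D2:**
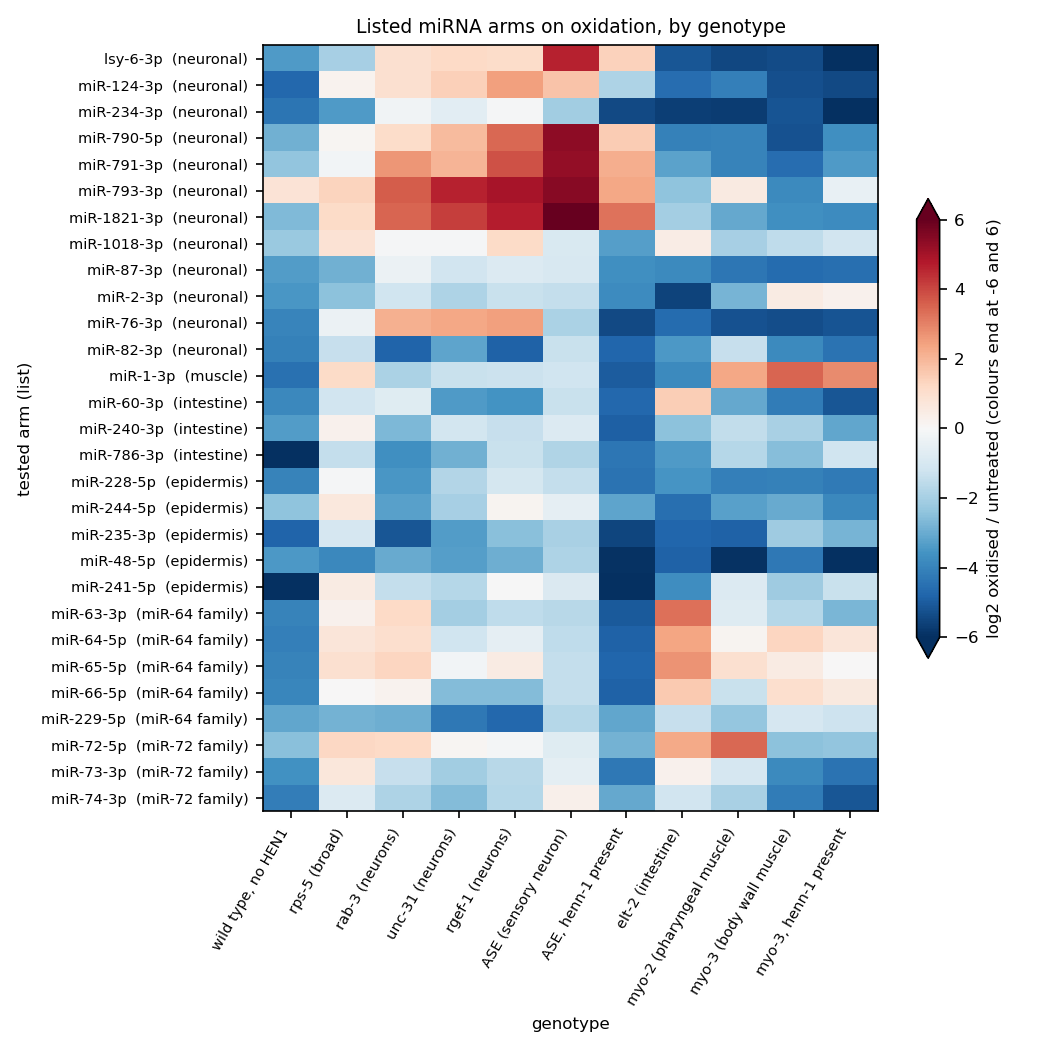
Log2 change on oxidation (colour, with limits at −6 and 6) of arms in 6 of the fixed lists (vertical axis, grouped by list) in the 11 genotypes (horizontal axis), with arms at 0 counts drawn at their fitted value. miR-1821-3p of the neuronal list was highest in ASE henn-1(0) worms (6.99) and miR-63-3p of the miR-64 family with the intestinal driver (3.30), while miR-2-3p of the neuronal list was highest with myo-3 (0.50).

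The 3 pan-neuronal drivers were also compared with each other. miR-60-3p was lower with unc-31 (−2.68 ± 0.57, adjusted p = 0.000781, edgeR) and with rgef-1 (−2.84 ± 0.57) than with rab-3, as were miR-60-5p (−3.95 ± 0.70 and −3.55 ± 0.70), miR-64-3p (−5.0 ± 0.75 and −4.44 ± 0.74), miR-80-5p (−3.91 ± 0.88 and −3.76 ± 0.87), miR-63-3p (−3.23 ± 0.48 and −2.70 ± 0.48) and miR-66-5p (−2.80 ± 0.40 and −2.78 ± 0.40). Of the 5 miR-64 arms all were lower with unc-31, 3 with RLE factors or total counts, and 4 with rgef-1 under each scaling, with the same counts adjusted over the list alone. Higher than with rab-3 were miR-1822-5p (4.65 ± 0.73), miR-1822-3p (3.79 ± 0.61) and miR-43-3p (3.11 ± 0.44) with unc-31 and miR-244-5p (3.41 ± 0.53), miR-250-3p (3.39 ± 0.52) and miR-228-5p (2.43 ± 0.34) with rgef-1. Between rgef-1 and unc-31, miR-53-3p was higher by 2.93 ± 0.66 and miR-1822-3p and miR-242-5p lower, at −2.59 ± 0.60 and −2.43 ± 0.54. In all 58 arms differed between unc-31 and rab-3 (24 higher, 34 lower), 61 between rgef-1 and rab-3 (34 and 27) and 11 between rgef-1 and unc-31 (7 and 4; 52 at an unadjusted p under 0.05). With the transgenic line as a replicate block the last number was 17. RLE factors moved the medians by 0.38, −0.11 and −0.48 and total counts by 0.29, −0.25 and −0.54, giving 39 and 25 or 32 and 26 arms for unc-31 against rab-3 and 4 and 7 or 3 and 7 for rgef-1 against unc-31. Without rab-3 library 32796 or 32797 the first number was 36 or 35, and without unc-31 library 32950 or 32954 or rgef-1 library 37022 the last was 6, 7 or 7. miR-53-3p lost its call without a filter on low counts (2.13) and without unc-31 libraries 32950 (2.07) or 32954 (2.58), miR-1822-3p without 32951 (−2.03) and miR-242-5p without 32953 (−1.77). miR-64-3p stood at −3.78 with unc-31 and −3.22 with rgef-1 without rab-3 library 32797. Without 32950 miR-1822-3p stood at 4.72 for unc-31 against rab-3 and at −3.52 for rgef-1 against unc-31, and without 32953 miR-1822-5p stood at 3.76.

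Each transgenic genotype was then set against wild type worms. In 8 of the 10 genotypes the worms also lacked henn-1, and no henn-1(0) worms without Ath-HEN1 were sequenced, so these differences do not separate the plant enzyme from the loss of the worm's own. miR-798-3p was lower than in wild type by −13.79 ± 0.85 with rps-5, −11.70 ± 0.84 with myo-3, −11.66 ± 0.81 with rab-3, −11.17 ± 0.82 with elt-2, −11.02 ± 0.84 with myo-2, −10.95 ± 0.82 with rgef-1, −10.45 ± 0.80 with unc-31 and −7.66 ± 0.75 with ASE, all in henn-1(0) worms. With henn-1 intact it stood at −0.54 ± 0.65 with myo-3 (adjusted p = 0.619, edgeR) and 0.20 ± 0.65 with ASE (adjusted p = 1, edgeR). miR-1-3p was higher by 7.98 ± 0.59 with myo-3 in henn-1(0) worms, 7.31 ± 0.58 with myo-3 and henn-1, 6.80 ± 0.57 with myo-2 and 5.64 ± 0.52 with rps-5. miR-124-3p was higher by 7.18 ± 0.56 with rgef-1, 6.14 ± 0.55 with unc-31, 5.68 ± 0.54 with rab-3 and 6.43 ± 0.55 with ASE, and miR-60-3p by 5.36 ± 0.60 with elt-2. lsy-6-3p was higher by 7.98 ± 0.69 with ASE in henn-1(0) worms and 4.74 ± 0.65 with ASE and henn-1, and miR-1821-3p by 9.64 ± 0.64 and 5.92 ± 0.59. miR-72-3p (7.53 ± 0.65) was higher with myo-2. Of these values, miR-798-3p with myo-3 and henn-1 passed the test as lower with RLE factors or DESeq2 (−2.21 in each), total counts (−2.57), no filter (−2.96) or without oxidised library 49402 (−2.59). Its fold also moved without myo-2 library 42756 (−12.42), myo-3 library 49406 (−12.56), rgef-1 library 37023 (−12.13), rps-5 library 42752 (−15.23) or unc-31 library 32953 (−9.83). Without wild type library 32794 miR-60-3p stood at 6.10 with elt-2, and with ASE lsy-6-3p stood at 8.67 in henn-1(0) worms and 5.42 with henn-1, and miR-1821-3p at 11.09 and 7.37. miR-124-3p with unc-31 stood at 5.01 without 32953 and miR-1-3p with myo-3 and henn-1 at 4.90 without 49402. Among henn-1(0) worms, arms that differed from wild type numbered 234 with rps-5 (173 higher, 61 lower), 225 with rab-3 (152 and 73), 221 with unc-31 (157 and 64), 223 with rgef-1 (169 and 54), 214 with elt-2 (119 and 95), 168 with myo-2 (94 and 74), 186 with myo-3 (91 and 95) and 210 with ASE (155 and 55). With henn-1 intact they numbered 83 with myo-3 (72 and 11) and 18 with ASE (17 and 1). These splits rested on the scaling. In the order just given, RLE factors moved the median by −2.60, −2.56, −2.18, −2.68, −1.58, −1.14, −0.67 and −1.91 in henn-1(0) worms and by −1.65 and −0.01 with henn-1, and gave 45 higher and 128 lower arms with rps-5, 66 and 141 with rab-3, 65 and 133 with unc-31, 69 and 140 with rgef-1, 77 and 163 with elt-2, 71 and 128 with myo-2, 75 and 124 with myo-3, 50 and 93 with ASE, and 46 and 130 with myo-3 and henn-1. Total counts moved it by −1.83, −1.65, −1.35, −1.89, −2.06, −2.10, −2.12, −1.46, −2.02 and −0.25 and gave 92 and 110, 93 and 124, 88 and 93, 93 and 118, 64 and 179, 48 and 168, 43 and 185, 76 and 80, 40 and 145, and 16 and 9. Without oxidised library 49402 the number for myo-3 with henn-1 was 170.

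The worm's own methyltransferase was examined by setting henn-1(0) worms against worms with henn-1 under the same driver. Of the 82 arms that had risen in wild type worms, 53 were lower and 2 higher without henn-1 with ASE, and 48 were lower with myo-3. miR-8198-3p differed by −8.54 ± 0.78 with ASE and −11.21 ± 0.85 with myo-3, miR-798-3p by −7.86 ± 0.75 and −11.16 ± 0.83, miR-78-3p by −7.71 ± 1.03 and −11.79 ± 1.16, and miR-62-3p by −2.59 ± 0.50 and −4.33 ± 0.52. With ASE miR-1-3p (3.82 ± 0.54), miR-124-3p (3.56 ± 0.52) and miR-60-3p (3.40 ± 0.58) were higher without henn-1, where the median arm stood at 2.05. With myo-3 miR-1-3p stood at 0.66 ± 0.52 (adjusted p = 0.59, edgeR), although it passed the test as higher with RLE factors or DESeq2 (1.64 in each) and without a filter on low counts (2.06), and miR-359-3p (2.29 ± 0.70, adjusted p = 0.0169) was the 1 arm that was higher. Arms lower without henn-1 numbered 56 with each driver, and 41 of them were lower with both, against 7.94 for independent sets (Fisher's exact test, two-sided, across arms, which are not independent replicates, p = 1.38e-30). These 2 comparisons share no library. Of the 41, 40 were among the 82 arms higher in wild type. With ASE 229 arms differed, 173 higher and 56 lower, and with myo-3 57 did, 1 higher and 56 lower. RLE factors moved the medians by −1.91 and 0.98 and gave 62 and 88 arms and 53 and 46, total counts moved that of ASE by −1.21 and gave 108 and 72, and the arms lower with both drivers were then 45 and 48. Without oxidised library 49402 of the myo-3 lines with henn-1, 102 arms differed, miR-1-3p passed the test (2.16), miR-62-3p stood at −2.85, miR-78-3p at −10.77, miR-798-3p at −9.96 and miR-359-3p at 5.23. Without 49406 miR-8198-3p stood at −15.95 with myo-3, without 42748 miR-78-3p stood at −8.62 with ASE, and miR-359-3p lost its call without library 49404 (1.41) or 49408 (2.07).

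**Figure D3:**
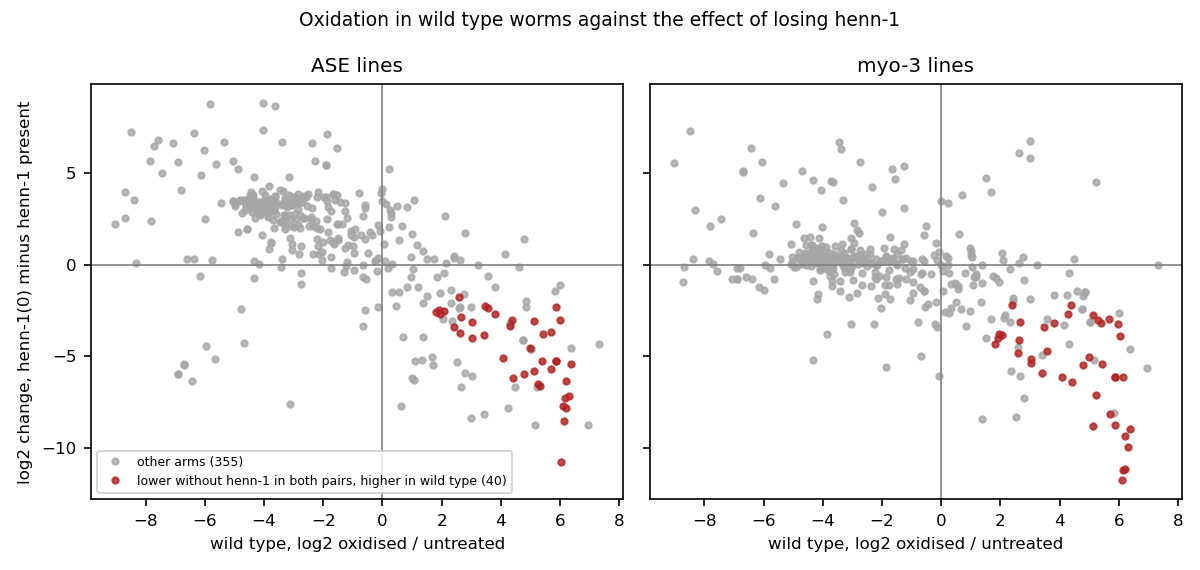
Difference between henn-1(0) worms and worms with henn-1 in the log2 change on oxidation (vertical axis; ASE and myo-3 drivers in separate panels) against the log2 change on oxidation in wild type worms (horizontal axis) for the 395 tested arms, drawn at their fitted values. The 40 arms higher in wild type and lower without henn-1 with both drivers (red) lie below 0 in both panels, and the other 355 are grey.

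Without oxidation, few arms passed the test between the rps-5 lines and wild type worms. This comparison was not part of the simulation, so the share of changes it missed is not known. miR-8198-5p was the 1 arm that differed, higher by 2.37 ± 0.53 in the rps-5 lines (adjusted p = 0.0258, edgeR; n = 3 and 2 libraries). The markers miR-1-3p (0.40 ± 0.34), lsy-6-3p (−0.27 ± 0.38), miR-60-3p (0.15 ± 0.36) and miR-124-3p (0.03 ± 0.33) did not pass the test, nor did miR-62-3p (0.34 ± 0.32). At an unadjusted p under 0.05, 57 arms differed, and DESeq2 called 23, 17 higher and 6 lower. RLE factors gave 5 higher and 2 lower arms and total counts 4, with a shift of the median by 0.14. miR-8198-5p lost its call without a filter on low counts (2.39), and without wild type libraries 32793 (2.78) or 34092 (2.06) or rps-5 library 42751 (2.12), when 0 arms passed, and without rps-5 library 42745 the number was 4.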

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

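The tests of HENN-1, of low depth with its 2 parts, and of arms with whole counts were chosen only after the result was seen, and the other tests below were set beforehand.

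miR-60-3p, the intestinal marker, stood 2.76 log2 units higher on oxidation with the rab-3 driver (−0.74; −0.96 with RLE factors) than with the mean of the unc-31 and rgef-1 drivers. The rab-3 transgene may be active in the intestine: 64 other arms that were higher with elt-2 than with rps-5 stood 1.62 (95% interval 1.21 to 2.20) above the remaining 329 arms in the same contrast, with a median of 0.96. Weaker oxidation of the rab-3 libraries would have raised muscle arms alike. However, elt-2 arms exceeded 54 muscle arms, with a median of −0.39, by 1.35 (0.75 to 2.00), which argues against it as the whole source. Muscle arms stood 0.29 (−0.07 to 0.75) above the arms outside both sets, so a part from weaker oxidation is not excluded. These intervals cover the spread of hairpins and not that of libraries. A difference between rounds of library preparation was not tested; the rab-3 libraries are numbered 32795 to 32798, the unc-31 libraries 32950 to 32954 and the rgef-1 libraries 37022 to 37025. Intestinal activity stays open as a hypothesis: the other 2 listed intestinal arms, miR-240-3p and miR-786-3p, fell with rab-3 (−2.70 and −3.70), but they also fell with elt-2 itself (−2.45 and −3.38).

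The 82 arms higher after oxidation in wild type worms could be methylated by HENN-1, for they stood below the other 313 arms when henn-1 was lost, by −6.14 (−7.16 to −5.45) with ASE and −3.49 (−4.55 to −3.18) with myo-3. To test low depth, the ASE henn-1(0) pair was used, also shallow at a mean of 1030000 counts against 636000. There 68.3% of them (56 of 82, 57.1 to 78.1) lay above the median arm, with 66.7% (32 of 48, 51.6 to 79.6) of those lower without henn-1 under myo-3 and 70.6% (24 of 34, 52.5 to 84.9) of the rest. These worms carry Ath-HEN1, which can also raise arms, so the shares cannot decide on depth. The oxidised ASE pair with henn-1 was about as shallow, at a mean of 950000 counts. The difference of −6.14 between the ASE pairs thus argues against depth as the source of the loss with ASE. Reads shared between loci could also add to it, since 33 of 82 arms against 38 of 313 had fractional values (odds ratio 4.85, 2.68 to 8.80, Fisher's exact test, two-sided, p = 5.22e-08), but 49 arms with whole counts fell below 275 others by −6.55 (−8.02 to −5.42) with ASE, so it is not the whole source. Overlap in position with annotated piRNA genes on the same strand was excluded as the main source, with 2 of 60 hairpins (0.406% to 11.5%) against 1 of 155. Reads from small RNA made at other positions were not tested in this way. How much of the rise in wild type worms came from HENN-1, depth or shared reads stays open.

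Other divisions of the libraries were tried for 2 results. In the rps-5 lines the real division called 227 arms and the highest of the others 11; 1 of 10 divisions of the 6 libraries reached 227, and 10 are too few for a share under 0.05. Among the 4 that part all 3 pairs the highest other number was 0. For pan-neuronal drivers against rps-5, 1 of 100 assignments of libraries, the real one, reached 226 arms, a share under 0.05, and the others had a highest number of 208 and a median of 0.

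The change on oxidation, tested as a difference between genotypes, differed from wild type worms in 234 arms with rps-5, 225 with rab-3, 221 with unc-31, 223 with rgef-1, 214 with elt-2, 168 with myo-2, 83 and 186 with myo-3 with henn-1 and without, and 18 and 210 with ASE. It differed from the rps-5 lines in 226 arms with the pan-neuronal drivers, 214 with elt-2, 193 with myo-2, 237 with myo-3 and 139 with ASE. Between henn-1(0) worms and worms with henn-1 it differed in 229 arms with ASE and 57 with myo-3, and between drivers in 58 for unc-31 and rab-3, 61 for rgef-1 and rab-3 and 11 for rgef-1 and unc-31.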

How the results depend on the processing

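The alternatives below moved a number of called arms by more than 1.5-fold, and the cause was not tested. In the rps-5 lines a fit of their own libraries called 134 arms in place of 227. For myo-3 with henn-1 against wild type, 83 arms became 176 with RLE factors, 185 with total counts, 189 without a filter and 175 with DESeq2. For ASE in henn-1(0) worms against wild type, 210 became 129 without a filter. Between henn-1(0) worms and worms with henn-1, 229 arms with ASE became 150 with RLE factors and 152 with DESeq2, and 57 with myo-3 became 99 with RLE factors, 122 without a filter and 119 with DESeq2. In untreated worms the single arm became 7 with RLE factors, 4 with total counts, 0 without a filter (edgeR; 57 at an unadjusted p under 0.05 with the filter) and 23 with DESeq2. For rgef-1 against unc-31, 11 became 7 without a filter, 17 with DESeq2 and 17 with the transgenic line as a replicate block. The block moved no other number by as much over 31 comparisons, where the ratio lay between 1 and 1.55. No paired analysis was possible for untreated worms, because lines are nested in genotypes.

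Left out 1 at a time, libraries gave the following lowest and highest numbers; where 1 sample remained in a group, it was assumed to vary like the other groups. Oxidised against untreated: wild type 230 and 277, rps-5 194 and 211, rab-3 256 and 260, unc-31 196 and 253, rgef-1 246 and 264, elt-2 263 and 276, myo-2 218 and 243, myo-3 with henn-1 201 and 216, myo-3 in henn-1(0) worms 241 and 257, ASE with henn-1 244 and 266 and ASE in henn-1(0) worms 110 and 122. Against wild type: rps-5 201 and 240, rab-3 204 and 227, unc-31 183 and 214, rgef-1 201 and 220, elt-2 186 and 206, myo-2 152 and 162, myo-3 with henn-1 73 and 170 (the latter without 49402), myo-3 in henn-1(0) worms 159 and 187, ASE with henn-1 12 and 20 and ASE in henn-1(0) worms 184 and 205. Against rps-5: pan-neuronal 215 and 231, elt-2 188 and 219, myo-2 156 and 196, myo-3 208 and 230, and ASE 91 (without 42750) and 141. Effect of henn-1: ASE 197 and 221, myo-3 51 and 102 (the latter without 49402). Between drivers: unc-31 and rab-3 35 (without 32797; 36 without 32796) and 53, rgef-1 and rab-3 44 and 54, rgef-1 and unc-31 6 (without 32950; 7 without 32954 or 37022) and 15. Untreated worms: 0 (without 32793, 34092 or 42751) and 4 (without 42745).

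RLE factors, total counts and DESeq2 called some arms in the opposite direction: 7, 4 and 8 in wild type worms, 4, 0 and 5 with myo-3 in henn-1(0) worms and 12, 3 and 12 with ASE and henn-1; and against wild type 3, 1 and 4 with rps-5, 1, 0 and 1 with rab-3, 5, 0 and 5 with unc-31, 3, 2 and 4 with rgef-1, 0, 2 and 0 with myo-2 and 0, 2 and 0 with myo-3 in henn-1(0) worms.

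Of 2983 values of 238 named changes under an alternative, 2896 kept their call and sign, 53 lost the call, 13 gained it and 21 changed sign. Of 227 named changes that passed the test, the fold of 62 moved by more than 1.5-fold when some single library was left out, as given beside them above. The changes of sign are these. miR-1-5p in wild type worms (−1.60) stood at 0.82 with RLE factors, 0.48 with total counts, 0.43 without a filter, 0.82 with DESeq2 and 0.05 in a fit of its own libraries. miR-8198-5p with ASE in henn-1(0) worms (0.17) stood at −0.04 without library 42747 and lowest at −0.61 without 42750, with the highest 0.65 without 42748. miR-798-3p with ASE and henn-1 against wild type (0.20) stood at −0.03 with total counts and −0.57 without a filter. miR-124-3p with ASE and henn-1 (−1.84) stood at 0.53 with RLE factors, 0.02 with total counts, 0.53 with DESeq2 and 0.07 in a fit of its own libraries. In the rps-5 lines (0.22) it stood at −0.03 with RLE factors, 0.00 without a filter, −0.03 with DESeq2 and −0.25 in a fit of their own libraries. In untreated worms (0.03) it stood at −0.01 without a filter, 0.00 without library 34092 and −0.01 without 36208, the lowest of the libraries left out in turn, with the highest 0.08 without 42751. miR-60-3p (0.15) stood lowest at −0.11 without 36208 and highest, among libraries left out in turn, at 0.34 without 42751.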

Other observations

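The test of the well-counted hairpins and the test against wild type below were set beforehand.

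The miR-35 family, made in oocytes and embryos, was lower in 8 of 8 arms with rab-3, elt-2, myo-2 and myo-3 in henn-1(0) worms, the same numbers adjusted over the list alone, with RLE factors leaving 7 with myo-2. With unc-31 5 were lower (3 with total counts), with rgef-1 6 (8 with RLE factors, 5 with total counts), with ASE and henn-1 8 (4 with either) and with myo-3 and henn-1 7 (6 with RLE factors), again the same over the list alone. The family median in the rps-5 lines was 0.67. In the shallow ASE henn-1(0) libraries the 8 values ran from −1.93 to −0.21, and 2 passed the edgeR test (1 adjusted over the list alone). Wild type worms, which lack the plant enzyme, had 6 of 8 lower (6 adjusted over the list alone, 2 with RLE factors or total counts). miR-42-3p stood at −3.73 ± 0.34 in wild type worms and at −3.03 ± 0.33, −3.93 ± 0.35, −3.94 ± 0.35 and −4.42 ± 0.35 with rab-3, elt-2, myo-2 and myo-3. In the miR-72 family, miR-72-5p rose by 3.43 ± 0.35 with myo-2 and 2.25 ± 0.34 with elt-2. With myo-3 in henn-1(0) worms 3 of 3 arms were lower (3 adjusted over the list alone, 2 with RLE factors), miR-73-3p at −3.83 ± 0.32 and miR-74-3p at −4.21 ± 0.30, close to −3.62 ± 0.31 (−4.36 without library 32794) and −4.16 ± 0.30 in wild type worms.

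The 3 pan-neuronal drivers, which share no library, moved much the same arms. Across arms, which are not independent replicates, their changes correlated at 0.832 (rab-3 and unc-31), 0.864 (rab-3 and rgef-1) and 0.904 (unc-31 and rgef-1). Arms higher with both numbered 113, 127 and 122, against 44.89, 56.48 and 48.97 for independent sets, and arms lower with both 115, 105 and 118, against 53.23, 47.72 and 47.72. Arms called in opposite directions numbered 7, 7 and 1. Some arms, such as miR-43-3p, fell in every genotype, and other drivers were not compared in this way. The agreement is therefore not shown to be particular to neurons.

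In lines with Ath-HEN1 and without henn-1, the arm of a hairpin with fewer counts rose more on oxidation than its partner, by a median of 1.12 log2 units (95% interval 0.83 to 1.40) over 178 hairpins, 127 of them in that direction. Low counts alone would not give this, because 29 hairpins with 2 well-counted arms showed 1.72 (1.05 to 2.63), 22 of them in the same direction. The plant enzyme could prefer passenger arms, but wild type worms, which lack it, showed 1.68 (0.87 to 2.05). These worms carry HENN-1, however, which could itself methylate some arms, so they are no control without a methyltransferase. Taken hairpin by hairpin, the lines with Ath-HEN1 less wild type gave a median difference of −0.03 (−0.46 to 0.55). An effect of the plant enzyme and its absence cannot be told apart by this test, which sets worms with 1 enzyme against worms with the other.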
